A study of Mus musculus with 6 samples.

How the data were processed

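Messenger RNA levels were measured by RNA sequencing in 6 libraries of 3T3-F442A cells, a mouse line of preadipocytes that can be differentiated into fat cells and that the labels call an adipocyte line. The 3 WT libraries came from the parental line and the 3 SWELL1 KO libraries from lines in which the SWELL1 gene (official symbol Lrrc8a) had been targeted with CRISPR/Cas9. Per the labels' protocols and the series' design text, cells were grown in RPMI with 10% FBS, RNA was extracted with TRIZOL, and sequencing was on an Illumina HiSeq. The labels call the 3 libraries of each group biological replicates. They do not say whether the KO libraries came from 1 clone or several, nor whether a differentiation step was applied. The sample names of the KO libraries carry the mark D3, which those of the WT libraries lack, and no label says what it stands for. KO minus WT therefore holds whatever else that mark stands for beside the genotype, and the p-values measure the spread between these libraries. A difference between clones would be read as a difference between genotypes.

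The authors deposited 1 table of 31097 rows with a value per library. The values are FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments) by inference, since no label and no header names the unit of the deposited table. Per the submitters' processing notes, TopHat, Cufflinks 2.02 and the build GRCm38 were used, and Cufflinks gives FPKM. The values were checked against this unit: they are never negative, are mostly not whole where above 0, and step in units that fall with gene length. Settings and the annotation release used by the authors are not given in the sources used here. Of the rows, 11679 carry an identifier made by Cufflinks and 19418 an Ensembl identifier, and 659 rows carry more than 1 gene name. A row was taken to stand for a gene when its other names were small RNAs, predicted or numbered clones (AC and AL clones included) or spellings of the same symbol. Other shared rows entered the test across all rows but not the gene lists. Whether the library kit kept strand is not given in the sources used here, so a gene and an overlapping antisense gene were not told apart.

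FPKM hold no counts, so depth was estimated from the low values of 1183 genes with a single transcript of at least 2500 bases, whose lowest values pile up at the worth of 1 fragment. This gave 17.2, 19.1 and 20.8 M fragments in WT replicates 1, 2 and 3 and 19.1, 25.9 and 18.4 M in SWELL1 KO replicates 1, 2 and 3. A transcript of 1 kb at 1 FPKM was therefore covered by 17.2 to 25.9 fragments, so values under 1 FPKM of short genes rest on few fragments. An exact 0 in this table is not a safe zero. Of 8117 rows that reached 5 FPKM in a library, 259 were at 0 in some but not all libraries of a group, and in 231 rows a 0 stood beside at least 5 FPKM in another library of the same group. For genes with a library at 0 each library's value is given, and they are said to be listed at 0, with no fold change between groups.

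The only comparison the design gives is KO against WT. Values were used as deposited, with no further scaling. Rows with a mean of at least 0.5 FPKM over the 6 libraries were tested (10515 rows) on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, a two-sided test and Benjamini-Hochberg adjustment, threshold 0.05. Log2 fold changes are KO minus WT on that scale, which understates the change of low genes. Means and SDs are of FPKM over 3 libraries. Gene lists were tested with camera on the same fit, with an inter-gene correlation of 0.01 and adjustment over the 26 of 34 lists with at least 5 tested members. Camera was repeated with the correlation estimated from the residuals, and fry was run beside it. No library pair looked like a repeat deposit of 1 library: within groups, 26.3% to 32.2% of genes at 10 FPKM or more differed by over 10%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for reading and drawing.

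The steps were tested on simulated data before use. In 10515 simulated genes for KO against WT, of which 200 were changed, 64.2% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, and 7.4% of calls were false. Simulated genes varied independently, and far fewer were changed than the 65.2% called in the real libraries. These rates need not hold there. When 1 list was lowered by 1 log2 unit, camera called that list alone with the preset and with the estimated correlation. In that simulation genes varied independently and no other gene was changed. False list calls among correlated genes, or where most genes move, were therefore not tested.

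Gene lists, the rule for named genes and all alternatives not said to be added were fixed before the data were examined. Named genes were the 5 LRRC8 genes, the 12 largest increases and 12 largest decreases past the threshold with groups that did not overlap and at least 5 FPKM in the higher group, without predicted or numbered clones and small RNAs, and up to 4 members of each list with the largest change among those past the threshold, or 2 members with the highest mean where none passed. Since most of the largest increases were listed at 0 in WT, the 12 largest increases and decreases among genes with no library at 0 were added after seeing the data. The closing section's added groups name only genes past the threshold with a log2 fold change of at least 0.5 in size. Some genes that these rules name are not reported here. List genes with no usable row were not analysed here (82 of 634 list members), and 8 more stood in rows shared with another gene; 9 members stood under another symbol in the table, 3 of them caveolae genes (Cavin1 as Ptrf, Cavin2 as Sdpr and Cavin3 as Prkcdbp), and 2 of the 9 were matched through RefSeq synonyms. Gene positions are from a GENCODE annotation of GRCm38.

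The alternatives were pseudocounts of 0.1 and 1, no filter on low values, a mean of at least 2 FPKM, median-ratio scaling, quantile normalization, limma without trend, limma with trend and robust, the replicate number as a block, and leaving out each library. A count-based test was planned only for count data and was not run because the values are FPKM. Leaving out rows with an exact 0 was added after seeing the data.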

Results

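RNA was sequenced from WT 3T3-F442A cells (3 libraries) and from the same line carrying a SWELL1 knockout (3 libraries), to ask how loss of SWELL1 changes gene expression in an adipocyte line. SWELL1, encoded by Lrrc8a, is a subunit of the volume-regulated anion channel, which opens when cells swell. Between 13005 and 13084 rows had a value above 0 in WT libraries and between 13858 and 14245 in KO libraries. Estimated depth was 17.2 to 20.8 M fragments in WT and 18.4 to 25.9 M in KO. A single row, the numbered clone AC166252.2, took 23.71%, 16.7% and 17.41% of the FPKM sum in KO replicates 1, 2 and 3, was at 2.1% in WT replicate 2, and was listed at 0 in WT replicates 1 and 3. Values below are means ± SD in FPKM, a unit inferred from the authors' use of Cufflinks and from the values, with n = 3 libraries per group, and adjusted p-values are from limma.

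The targeted gene could not be read on its own. Lrrc8a lies on chromosome 2 from 30237715 to 30263790 (GRCm38) and shared its row with the neighbouring Phyhd1 (30266203 to 30282149) and Nup188 (30286397 to 30344266). That row stood at 32.5, 35.0 and 33.2 FPKM in WT replicates 1, 2 and 3 and at 28.8, 28.0 and 27.3 FPKM in SWELL1 KO replicates 1, 2 and 3 (log2 fold change -0.26, SE 0.04, adjusted p = 0.00322). The call was lost under quantile normalization (log2 fold change -0.10, adjusted p = 0.106). The row mixes 3 genes, and an edit that shifts the reading frame need not lower RNA, so these values do not check the knockout labels. Of the other subunits, Lrrc8d, in a row shared with a RIKEN transcript, fell from 5.25 ± 0.45 to 2.09 ± 0.28 (adjusted p = 0.00024). Lrrc8c rose from 2.75 ± 0.11 to 3.62 ± 0.18 (adjusted p = 0.00509). Lrrc8b was at 1.62 ± 0.15 and 1.85 ± 0.02 (adjusted p = 0.162). Lrrc8e was untested, at 0.0149, 0 and 0 in the WT libraries and 0.00446, 0.0198 and 0.0140 in the KO libraries.

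Egfr, the receptor for epidermal growth factor (chromosome 11, 16752203 to 16918158), fell 106-fold, from 172 ± 12.1 to 1.62 ± 0.22 FPKM. The growth factor Igf2 (chromosome 7, 142650766 to 142666816) fell 57.4-fold, from 466 ± 14 to 8.11 ± 0.23. Fabp4, the fatty acid binding protein of fat cells (chromosome 3, 10204088 to 10208576), fell 46.3-fold, from 159 ± 27.9 to 3.44 ± 0.96. The smooth muscle actin Acta2 fell 39.7-fold, from 74.7 ± 6.16 to 1.88 ± 0.39, and the collagen gene Col12a1 fell 66.6-fold, from 103 ± 2.38 to 1.55 ± 0.10. In the other direction, Dpt, which encodes the matrix protein dermatopontin (chromosome 1, 164796644 to 164824266), rose 71.9-fold from 0.83 ± 0.17 to 59.5 ± 4.65. The chemokine gene Ccl2 (chromosome 11, 82035571 to 82037453) rose 36.7-fold from 2.82 ± 0.70 to 104 ± 12.3, and the caveolin gene Cav2 (chromosome 6, 17281185 to 17289115) rose 11.5-fold from 103 ± 7.83 to 1187 ± 155. Every one of these 8 genes had an adjusted p of 1.09e-05 or less.

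**Figure D1:**
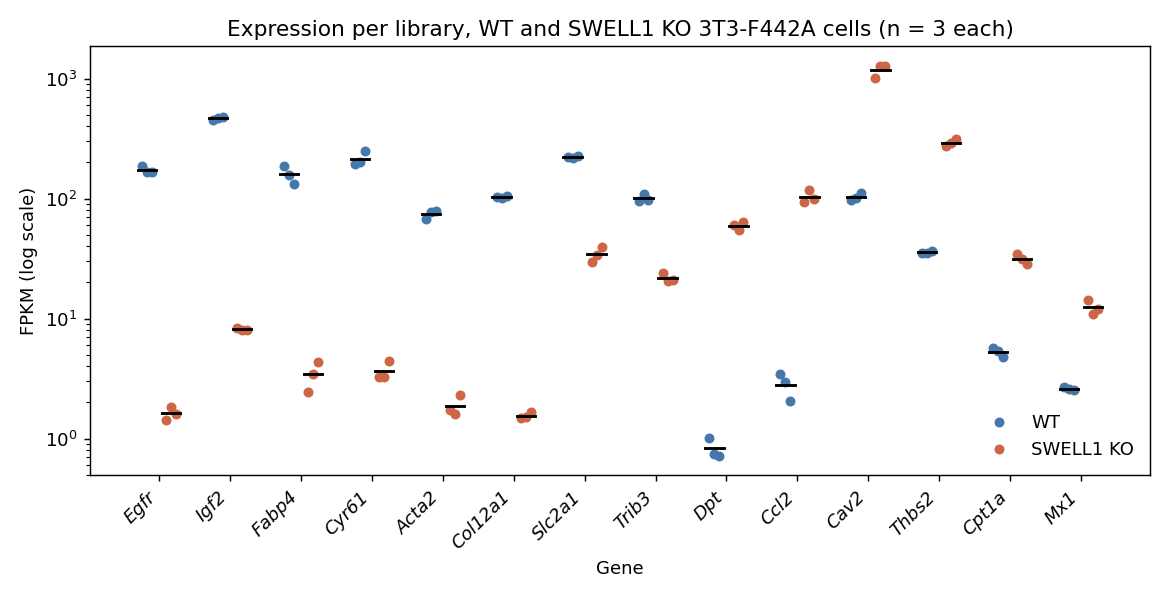
FPKM on a log axis for 14 genes in the 3 WT libraries (blue) and the 3 SWELL1 KO libraries (orange), with 1 point per library and a black bar at the group mean. The groups do not overlap for any of the 14 genes; Egfr lay between 165 and 186 FPKM in WT and between 1.42 and 1.85 in KO, and Dpt between 0.717 and 1.02 in WT and between 54.6 and 63.9 in KO.

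Among genes with no library at 0, a set added after seeing the data, the 12 largest increases also held Sertad4 (29.4-fold), Mterfd2 (13.9-fold) and the glutathione transferase gene Gsta4 (15.1-fold, from 3.17 ± 0.50 to 47.9 ± 3.18). Further increases were Cd300lb (42.2-fold, from 0.26 ± 0.07 to 10.9 ± 1.85), the carboxylesterase gene Ces1f (32.2-fold, from 0.35 ± 0.06 to 11.4 ± 0.82) and the phosphodiesterase gene Pde5a (128-fold, from 0.053 ± 0.016 to 6.74 ± 0.07). The rest were Ngef (135-fold, from 0.047 ± 0.023 to 6.34 ± 3.03), Plb1 (77.9-fold, from 0.078 ± 0.017 to 6.07 ± 1.23) and a row shared by Evi2a and Evi2b (0.0427, 0.0133 and 0.0707 FPKM in WT, 5.57, 6.95 and 5.14 in KO). Among the 12 largest decreases were also Cyr61 (59-fold), Pi15 (127-fold, from 27.3 ± 1.46 to 0.22 ± 0.02), Ptx3 (31.5-fold, from 404 ± 5.81 to 12.8 ± 2.22), Fam110c (34.1-fold), Rgs2 (30-fold) and Nos2 (78.8-fold, from 16.5 ± 0.43 to 0.21 ± 0.08). Folds over means under 1 FPKM rest on low values and exceed the change on the tested scale. The rule written beforehand gave 10 increases that were listed at 0 in all 3 WT libraries: Romo1 (109, 85.6 and 105 FPKM in KO), a row shared by Mrps34 and Nme3 (51.6, 46.0 and 35.5), Ppil3 (28.2, 17.5 and 18.5), a row shared by Ovgp1 and Wdr77 (25.1, 20.1 and 14.5), Isca2 (17.7, 18.6 and 18.5), Ccdc58 (22.8, 18.1 and 14.3), a row shared by Mettl23 and Mfsd11 (14.7, 14.6 and 12.9), Tor1aip1 (12.7, 16.5 and 11.6), Sh2b3 (12.3, 14.0 and 13.2) and Fam116a (16.3, 11.9 and 11.6). Among its decreases, Igfbp3 (30.1, 23.3 and 26.5 in WT), Psph (21.0, 23.2 and 23.1), Alkbh1 in a row shared with a RIKEN transcript (19.04, 18.4 and 17.6) and Ormdl2 (13.3, 17.9 and 15.5) were listed at 0 in all 3 KO libraries. Plekha2 (29.0, 28.3 and 26.8 in WT) was listed at 0, 1.43 and 0 in KO, and the noncoding RNA Meg3 (39.8, 34.7 and 50.3 in WT) at 0.190, 0 and 0.0975. Of rows at or above 5 FPKM in a library, 30 were at 0 in all WT and no KO libraries and 22 at 0 in all KO and no WT libraries, and 34 of the 45 such rows with a position overlapped another protein-coding gene.

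Of 10515 tested rows, 6860 (65.2%) passed the threshold, 2998 higher and 3862 lower in KO. With at least a 2-fold change there were 791 higher and 1000 lower as deposited, 885 and 876 under median-ratio scaling, and 857 and 898 under quantile normalization. The groups did not overlap for 71.8% of tested rows, against 10% by chance. The first principal component held 66.3% of the variance and separated the groups. Pearson's r across genes, which are not independent replicates, was 0.946 to 0.967 within groups and 0.856 to 0.874 between them. Under quantile normalization 50.4% of called genes were higher in KO, against 43.7%. The 3 libraries of a group bound what these p-values cover, since no source says whether the KO libraries share a clone or what the mark D3 in their sample names alone stands for.

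Genes of glycolysis and of the response to low oxygen fell together: 15 of 19 tested members fell and 1 rose (camera adjusted p = 2.91e-05; adjusted p = 0.611 with an estimated correlation). The glucose transporter gene Slc2a1 fell from 222 ± 4.20 to 34.3 ± 4.99, the hexokinase gene Hk2 6.27-fold, and the oxygen sensor gene Egln3 from 35.1 ± 3.69 to 2.02 ± 0.46. Ankrd37 was listed at 0 in all KO libraries and at 12.5, 11.5 and 12.1 FPKM in WT. Genes of the unfolded protein and integrated stress response fell in 19 of 21 cases and rose in 2 (adjusted p = 7.74e-05; adjusted p = 0.626 with an estimated correlation). Trib3 fell 4.57-fold, Chac1 5.78-fold, Manf, a secreted protein of the endoplasmic reticulum stress response, from 245 ± 16.2 to 57.2 ± 2.69, and the asparagine synthetase gene Asns from 214 ± 18.7 to 60.1 ± 3.18. Phgdh rose 1.5-fold and Slc7a11 2.71-fold.

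Cholesterol synthesis genes fell in 16 of 18 cases and rose in none (adjusted p = 8.44e-04; adjusted p = 0.68 with an estimated correlation). Cyp51 fell from 18.9 ± 1.95 to 4.64 ± 0.78, Insig1 3.51-fold and Sc5d 2.86-fold. Of 8 tested adipocyte identity genes 5 fell and 1 rose, without a list call (adjusted p = 0.136). The filter on low values bore on this result, since 17 members had a row and 8 were tested. With no filter camera called the list (median log2 fold change -1.18, adjusted p = 0.000862). Besides Fabp4, the regulator gene Pparg fell from 1.83 ± 0.73 to 0.13 ± 0.06. Adipoq was at 1.87, 1.55 and 1.26 FPKM in WT and at 0.0443, 0 and 0 in KO (adjusted p = 0.000108). Plin4 was at 0, 1.74 and 0 FPKM in WT and at 5.04, 5.21 and 5.06 in KO (adjusted p = 0.00821). Of 13 early adipogenic regulators 5 fell and 3 rose (adjusted p = 0.862): Klf9 fell from 92.5 ± 5.35 to 29.0 ± 2.94, Cebpd 3.08-fold and Kdm4b 2.63-fold, and Ebf1 rose 2.19-fold. In fatty acid and triglyceride synthesis 7 of 15 fell and 6 rose (adjusted p = 0.828), with Dgat2 5.77-fold, Fads2 2.77-fold, Lpin1 2.34-fold and Acsl1 2.11-fold lower; the list median changed sign under quantile normalization. In lipolysis and fatty acid oxidation 7 of 13 rose and 2 fell over all genes, and 10 passed adjusted over the list alone (camera adjusted p = 0.0639). The carnitine palmitoyltransferase gene Cpt1a rose from 5.30 ± 0.44 to 31.3 ± 3.02, the lipid droplet gene Plin2 3.46-fold, and Acaa2 3.04-fold, while Pnpla2 fell 1.86-fold.

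Of 16 tested YAP and TAZ targets, genes known to respond to the coactivators of the Hippo pathway, 11 fell and 4 rose (adjusted p = 0.145). Cyr61 fell from 214 ± 29.9 to 3.63 ± 0.68, Amotl2 9.29-fold and Ankrd1 6.39-fold, and Igfbp3 was listed at 0 in KO. Smooth muscle markers fell in 5 of 7 cases and rose in 1 (adjusted p = 0.179); Myl9 fell from 17.8, 23.6 and 22.3 FPKM to 0.260, 0.269 and 0.760, Cnn2 fell 1.73-fold and Smtn rose 1.5-fold. In collagens and extracellular matrix 17 of 28 fell and 7 rose, 26 adjusted over the list alone against 24 over all genes (adjusted p = 0.25). Mmp3 fell 11.4-fold and Timp1 from 806 ± 44.7 to 113 ± 6.57, while Thbs2 rose from 35.8 ± 0.71 to 291 ± 20. Among integrins and focal adhesion genes 8 of 18 fell and 7 rose, 16 adjusted over the list alone against 15 (adjusted p = 0.862, median -0.05 and mean 0.07; the median changed sign under both scalings). Itgb7 rose from 1.77 ± 0.24 to 24.9 ± 2.51, Itgb3 3.06-fold and Itga6 2.3-fold, and Itga7 was at 11.6, 11.9 and 12.1 FPKM in WT and at 0, 0 and 2.07 in KO. Caveolae genes, which shape membrane pits, rose in 4 of 6 tested cases with none falling (camera adjusted p = 0.00978, and 0.626 with an estimated correlation). The caveolin gene Cav1, 1 of the 7 members of the list, was not analysed here. Beside Cav2, Cavin2 rose 2.53-fold, Cavin3 2.21-fold and Pacsin2 1.36-fold. Cavin1 (161 ± 11.7 and 181 ± 11.3, limma adjusted p = 0.0853) and Ehd2 (27.5 ± 9.7 and 45.6 ± 11.5, limma adjusted p = 0.0775) did not pass. Preadipocyte and stromal markers rose in 5 and fell in 3 of 11 cases (adjusted p = 0.542), with Pi16 3.62-fold and Gsn 1.87-fold higher and Thy1 2.01-fold and Dlk1 1.72-fold lower.

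Proliferation genes fell in 19 of 26 cases and rose in 1 (adjusted p = 0.0011; adjusted p = 0.68 with an estimated correlation). Aurka fell from 30.5 ± 2.27 to 8.97 ± 0.58, Ccne1 3.41-fold, Aurkb 3.18-fold and Ccnb2 2.55-fold, while Pcna was at 31.5 ± 0.21 and 31.4 ± 1.46 (adjusted p = 0.954). Interferon response genes rose in 12 of 18 cases and fell in 4 (adjusted p = 0.00512; adjusted p = 0.68 with an estimated correlation). Mx1, an antiviral GTPase, rose from 2.60 ± 0.08 to 12.4 ± 1.71, and Irf7 was listed at 0 in WT and at 9.59, 12.2 and 9.50 FPKM in KO. Psmb8 (20.3, 36.8 and 38.0 FPKM in WT, 0, 0 and 8.69 in KO) and Psmb9 (8.33, 8.86 and 8.15 in WT, 0, 5.41 and 0 in KO) were among the 4 lower members and lost their calls in 4 and 5 of the 6 fits that left out 1 library: Psmb8 without WT replicate 2 or 3 or KO replicate 1 or 2 (adjusted p from 0.0523 to 0.054), and Psmb9 without WT replicate 1, 2 or 3 or KO replicate 1 or 3 (adjusted p from 0.0933 to 0.115). Psmb9 also lost its call with a pseudocount of 0.1, with no filter on low values and with the robust fit (adjusted p from 0.0506 to 0.0614). Inflammatory and NF-kappaB targets rose in 6 and fell in 6 of 17 cases (adjusted p = 0.862): Ccl2 rose, while Il6 fell from 13.0 ± 0.95 to 0.41 ± 0.16, Lcn2 5.94-fold and Ptgs2 4.55-fold. The p53 targets rose in 7 and fell in 5 of 15 cases (adjusted p = 0.455), with Plk2 4.68-fold and Fas 2.82-fold lower and Sesn1 3.62-fold and Eda2r 2.19-fold higher. Immediate early genes fell in 9 and rose in 5 of 17 cases (adjusted p = 0.648), led by Nr4a1, which fell from 124 ± 4.85 to 30.1 ± 17.2, with Fos, Fosb and Ier3 lower as well.

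Insulin and PI3K-AKT-mTOR genes fell in 11 and rose in 9 of 31 cases (adjusted p = 0.929), and the list median changed sign under both scalings. The phosphatase gene Ptpn1 fell 4.21-fold and the adaptor gene Grb10 from 1.13 ± 0.10 to 0.028 ± 0.015. Chloride channel and volume regulation genes fell in 8 and rose in 7 of 19 cases over all genes, 16 adjusted over the list alone (adjusted p = 0.921). Clic4 fell from 65.7 ± 1.81 to 29.2 ± 0.82, while Aqp5 and Clcn5 rose 5.23-fold and 2.37-fold. The hypertonic response list held the regulator gene Nfat5 and its targets. Of its 6 tested members 4 rose and 2 fell (adjusted p = 0.289). Hspa4l rose from 11.0 ± 1.94 to 34.3 ± 4.76, Nfat5 2.2-fold and Slc6a6 1.51-fold, and Sgk1 fell 1.95-fold. In the TGF-beta and BMP list 8 of 20 fell and 5 rose (adjusted p = 0.942), with examples in Fst (6.37-fold lower), Inhba (3.57-fold lower) and Tgfb3 (3.98-fold higher). Wnt genes fell in 4 and rose in 3 of 10 cases (adjusted p = 0.985): Sfrp2 and Sfrp1 fell 15.1-fold and 23.8-fold and Fzd1 rose 2.41-fold. Tcf7l2 rose 1.59-fold, and its call was lost without WT replicate 2 or 3 or KO replicate 1 or 3 (adjusted p from 0.0557 to 0.0736). Notch genes fell in 4 and rose in 3 of 9 cases (adjusted p = 0.921), with Notch3 6.94-fold and Jag1 3.31-fold lower and Notch2 2.21-fold higher; Notch4 rose from 0.412, 0.0697 and 0.133 FPKM to 1.07, 1.06 and 0.938. The medians of the Wnt and TGF-beta lists changed sign under a scaling.

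Oxidative phosphorylation genes fell in 12 and rose in 3 of 21 cases (adjusted p = 0.227; median -0.26, mean 0.00): Ndufa4, Ndufa9 and Cox6a1 fell 1.71-fold, 1.66-fold and 1.58-fold, and Cox5b rose 1.77-fold. Cytosolic ribosomal protein genes, taken as a mark of RNA composition, fell in 13 and rose in 1 of 18 cases (adjusted p = 0.00884; adjusted p = 0.68 with an estimated correlation; adjusted p = 0.246 under quantile normalization). Rpl18, Rps3, Rpl15 and Rps16 fell 1.54-fold, 1.51-fold, 1.4-fold and 1.35-fold. Mitochondrially encoded genes were not analysed here. Markers of other cell types were mostly below the filter. Sox9 rose from 1.79 ± 0.33 to 13.5 ± 0.79 and Spp1 fell from 4208 ± 48.9 to 3173 ± 294 among osteoblast and chondrocyte markers, with Dmp1 at 0.0213, 0 and 0 FPKM in WT and at 1.21, 0.821 and 1.04 in KO. Lyz2 of macrophages fell from 1.29, 1.64 and 1.61 FPKM to 0.317, 0.101 and 0.0948, Vwf of endothelium rose from 0.42 ± 0.09 to 1.71 ± 0.02, Krt7 of epithelium fell from 4.35 ± 0.14 to 0.33 ± 0.17, and Krt8 was listed at 0 in WT and at 1.49, 1.17 and 1.30 in KO. Tbx15 of brown fat rose 1.33-fold. Tnnt1 of skeletal muscle was at 0.38 ± 0.11 and 0.80 ± 0.18 (adjusted p = 0.0329), and its call was lost without WT replicate 2 or 3 or KO replicate 1 or 2 (adjusted p from 0.0531 to 0.0863) and under quantile normalization (adjusted p = 0.0979).

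**Figure D2:**
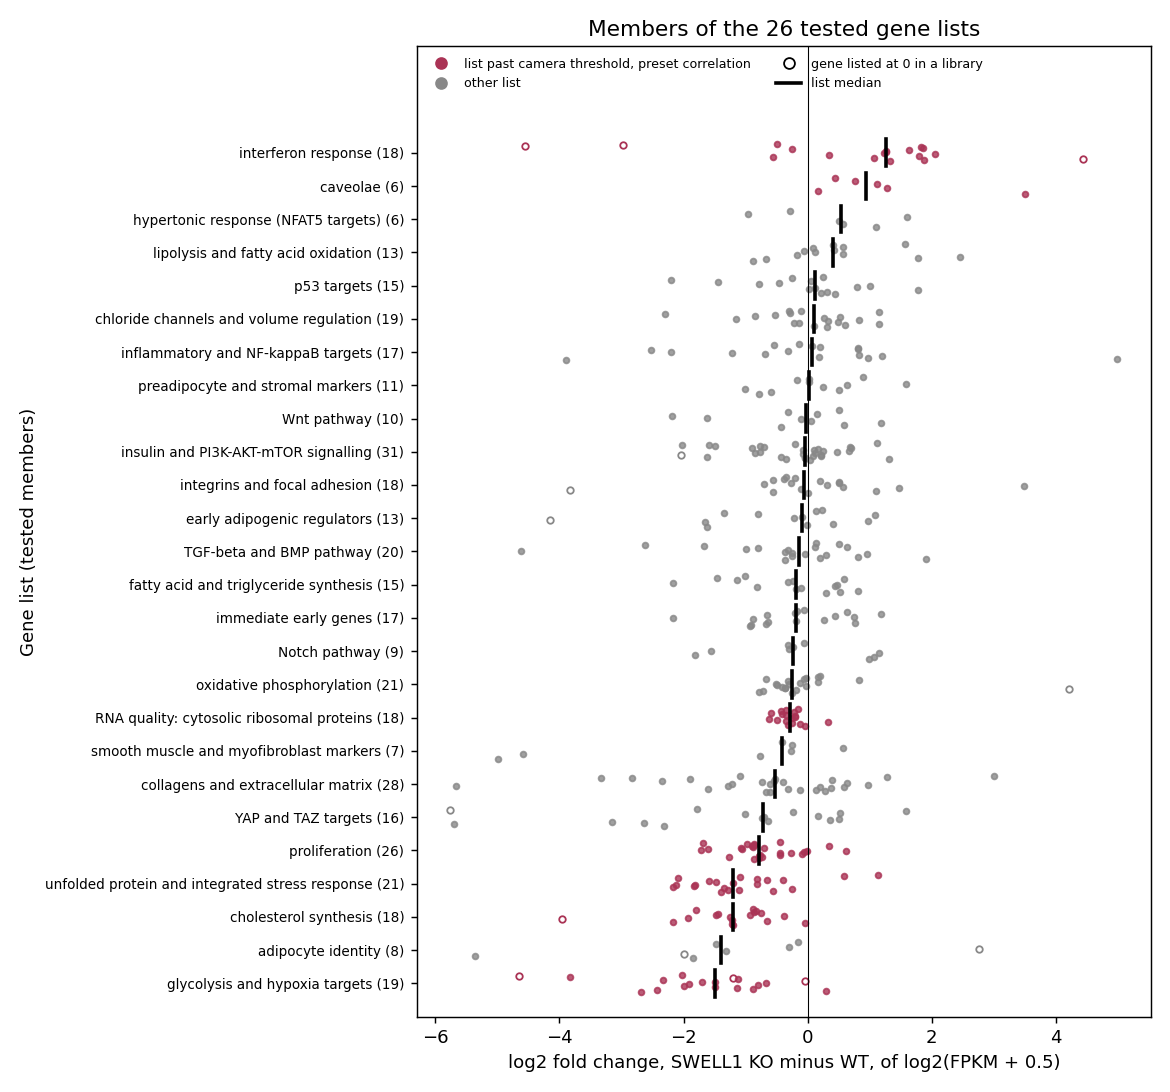
Log2 fold change (SWELL1 KO minus WT, on log2(FPKM + 0.5)) of the tested members of 26 gene lists, 1 point per gene, open where a library was listed at 0, with a black bar at the list median. Red lists passed camera with the preset correlation; medians ran from -1.49 for glycolysis and hypoxia to 1.26 for interferon response.

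Of the 26 lists tested 7 passed camera, 5 lower and 2 higher in KO, and 0 of them held with an estimated correlation. With the preset correlation, camera also called 1 to 5 lists in every other split of the 6 libraries into 3 and 3. Each of those splits mixed WT and KO libraries. Fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, passed 24 lists; those it did not were p53 targets and the inflammatory list. In the lists for which no other number is given, the count adjusted over the list alone equalled the count over all genes, except that skeletal muscle markers had 2 against 1. Median and mean differed in sign for LRRC8 subunits (0.15 and -0.22), integrins (-0.05 and 0.07), chloride channels (0.11 and -0.01), p53 targets (0.13 and -0.01) and inflammatory targets (0.07 and -0.09), and camera, not run on the LRRC8 subunits, pointed up for the others and for Wnt genes, whose median was -0.03 and mean -0.22.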

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

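Of the alternatives below, leaving out rows with an exact 0 was chosen after seeing the data. Counts of genes past the threshold stayed within 1.5 times of 6860 under all alternatives that were run, from 6106 with a mean of at least 2 FPKM to 7595 with no filter on low values, and genes changed at least 2-fold ranged from 1407 to 2030 around 1791. Leaving out 1 library gave 6325 to 6528 genes and 1754 to 1816 with at least a 2-fold change. Leaving out rows with an exact 0 gave 6778 and 1582. With the replicate block, 6534 genes passed, of which 6369 were shared with the 6860; residuals of same-numbered libraries correlated at 0.003, 0.012 and -0.093, so the number was not taken to pair libraries. The number of lists past camera was 12 with no filter on low values, where 16722 genes were tested, and 0 with the inter-gene correlation estimated; leaving out 1 library gave 7 to 8. The row with Lrrc8a had a log2 fold change of -0.10 under quantile normalization (adjusted p = 0.106, past the threshold in the other 15 alternatives), and -0.28 to -0.23 when 1 library was left out. The share of called genes higher in KO was 50.4% under quantile normalization, against 43.7%; the median log2 fold change of tested rows was -0.07 as deposited, -0.01 with median-ratio scaling and -0.00 with quantile normalization. The medians of 5 lists changed sign under a scaling, and none of these lists was called. The ribosomal protein list lost its call under quantile normalization (-0.14, adjusted p = 0.246), and the lipolysis list gained one in 4 alternatives (adjusted p from 0.026 to 0.0498). With no filter 5 further lists gained one (adjusted p from 0.000862 to 0.0434). They were adipocyte identity, collagens and extracellular matrix, YAP and TAZ targets, smooth muscle markers and oxidative phosphorylation. The cause of the changes under quantile normalization was not tested. Values without counts limit what can be said of genes under 1 FPKM.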

Other observations

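The tests of scaling, of zeros that fall on any libraries alike and of imprinted genes were chosen after their results had been seen, as were the gene groups named first below, apart from the HIF targets. Genes of glutathione and foreign-compound metabolism rose in 15 of 19 tested cases and fell in 1 (median log2 fold change 1.26), led by Ces1f, Gsta4 and Aox3 (33.7-fold); Nqo1 rose 2.47-fold and Hmox1 fell 1.72-fold. Among iron storage and lysosomal genes 9 of 17 rose and 3 fell: the ferritin gene Fth1 rose from 2491 ± 81.3 to 5328 ± 168 FPKM, Ctsl from 2752 ± 291 to 5164 ± 694, and Lamp1 and Lamp2 1.86-fold and 1.96-fold, while the protease genes Ctsa and Ctsz fell 2.13-fold and 2.1-fold (list median 0.19). In the EGF receptor family and its ligands, Egfr fell and Btc rose from 0.024 ± 0.008 to 1.29 ± 0.07, while 4 of 8 tested genes did not pass the threshold. Of 8 tested IGF ligands, receptors and binding proteins 5 fell and 2 rose, among them Igf2r, from 42.2 to 80.5 FPKM. List medians were ranked among 10000 random lists matched for expression. The glutathione group stood at percentile 100, the iron and lysosomal group at 96.61, the EGF group at 49.72 and the IGF group at 18.01. The groups were picked after seeing the data and the random lists drew genes independently, so these ranks only describe the groups.

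Glycolysis and hypoxia genes were lower in KO. Scaling as the cause is argued against, since the list median was -1.37 or lower under both scalings. As a hypothesis, transcription of HIF targets may be lower in the KO cultures. In a test chosen beforehand, 27 HIF targets outside glycolysis and outside the fixed lists had a median of -1.54, below all of 10000 expression-matched random lists. Those random lists drew genes independently, so genes regulated together were not allowed for, and the rank is not a p-value. Of the HIF targets 22 fell and 1 rose. The 1 that rose was Pfkfb4, which like the lower Pfkfb3 of this list encodes a regulator of glycolysis. Fam162a, Ero1l and Adm fell 7.29-fold, 5.27-fold and 4.58-fold. Whether the genotype, the clone or the culture (density, medium, oxygen) lies behind this was not tested, since each goes with the groups.

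Many genes passed the threshold. Of the 10 ways to split 6 libraries into 3 and 3, 1, the real one, gave as many genes (6860, highest other 3). The same held for genes with at least a 2-fold change (1791, highest other 3) and for lists (7, highest other 5). Every other split had WT and KO libraries on both sides, so the group difference widened its residual spread. Few gene calls there were fixed in advance, and these gene counts do not measure chance. Those splits also kept part of the group difference, so whether their 1 to 5 list calls are false was not tested. Besides, 10 splits are too few for a share under 0.05. In a test written beforehand, chromosome medians of the log2 fold change differed from that of all genes at an adjusted permutation p under 0.05 on 14 of 20 chromosomes, and 8 of them, chromosomes 1, 3, 4, 6, 7, 10, 12 and 15, shared p = 0.0001, the smallest that 10000 permutations can give (adjusted p = 0.00025). The difference reached 0.445 on chromosome 10, where 253 genes rose, 86 fell and 20 Mb bins ran from 0.252 to 0.566, and lay between -0.264 and 0.195 on the other 7. The permutation p-values take genes as units, which are not independent replicates. Small shifts, such as -0.075 on chromosome 2, may therefore be overcalled. A gain of chromosome 10 in the KO line is a candidate explanation for that chromosome, but shifts of whole chromosomes do not account for most calls: after each chromosome was centred, the count was 0.99 times that before. A copy number was not measured, and regulation along a chromosome stays open.

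Some genes were listed at 0 in every library of 1 group. For the 73 rows with exactly 3 zeros and at least 5 FPKM in a library, zeros that fall on any libraries alike are argued against. In 71.2% of them the zeros filled 1 group, against 10% by chance. This covers those rows as a set and not each of them. Of all 311 rows at or above 5 FPKM with a 0, 259 were at 0 in some but not all libraries of a group. In a test written beforehand, 75.6% of rows at 0 in every library of 1 group and in none of the other overlapped another protein-coding gene, against 25.2% of other rows at 5 FPKM or more (two-sided Fisher's exact test, p = 2.57e-12), so reads moved between overlapping genes are a candidate explanation that differs between groups. No single row was traced, and absence of the transcript in these libraries stays open.

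Imprinted genes drew attention through Igf2, Meg3 and Grb10, and H19 fell 11.3-fold. Of 16 tested, 12 fell, 7 of these at least 2-fold, and 2 rose. The list median of -0.72 stood at percentile 0.16 of 10000 random lists matched for expression. The list was picked after such members had been seen and the random lists drew genes independently, so this rank only describes it. Without the 7 members whose values had been seen, 2 of 9 tested imprinted genes (22.2%) changed at least 2-fold, against 17% of all other tested genes, in which those 7 were counted (two-sided Fisher's exact test, p = 0.656), which does not separate them from other genes at this number.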
